A study of Mus musculus with 4 samples.

How the data were processed

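Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open DNA, in a mouse lung adenocarcinoma cell line derived from a KP lung tumour and carrying Cas9, which the labels call KPC cells. CRISPR activation was directed at Malat1 (group mA2 dRNA) or at luciferase, a sequence the mouse genome lacks (group Con dRNA), and the series describes 2 biological replicate cell samples in each of the 2 groups, 4 libraries in all. The library preparation used a commercial ATAC-seq kit, per the labels' protocols.

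FastQC, Bowtie2, Picard, MACS2, DiffBind, ChIPseeker and deepTools are listed without versions, and mm10 as the genome build, per the submitters' processing notes. The roles of these tools, the handling of duplicate and mitochondrial reads, the shift of read ends to the insertion site, the normalization of the libraries, and whether peaks were called per library or on pooled reads are not given in the sources used here. The authors' deposited table held 80881 peaks, of which 99.8% were windows of 401 bp. For every peak it gave the log2 of the authors' mean normalized read count in each group and over both groups, per the file headers. It further gave the authors' log2 fold, p-value and adjusted p-value for the Malat1 guide against the luciferase guide, an annotation class, the assigned gene and the distance in bp from its transcription start site. The deposited adjusted p-value matched a Benjamini-Hochberg adjustment of the deposited p-value over all peaks, with a largest gap of 7.40e-06. The authors' log2 fold was smaller than the difference of their group means, with a median ratio of 0.77 over called peaks and 0.10 over the others, so the fold values printed here are ratios of the deposited group means and not the authors' fold. The header names the groups dmA12 and dLuc where the sample labels have mA2 and Con. They were taken as the same groups because the series holds a single contrast of Malat1 with luciferase, and for dmA12 the identity rests on that alone.

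The table also held 4 columns of per-library values whose names match no sample label, and these were not used in any step, since columns were assigned to samples and groups by their names and never by their values. On inspection their means in pairs closely matched the authors' group means, so leaving them out was a choice of this re-analysis and not a limit of the table. Hence no spread between libraries, no depth per library and no error per value was computed, and the planned fits per library (a count model or limma with a trend, a replicate block, each library left out in turn, further library scalings and an estimated correlation for the set tests) were not run. The authors' p-values took their place, and the test behind them is not given in the sources used here. The sum over peaks of the authors' mean normalized reads was 13278580 with the Malat1 guide and 12465466 with the luciferase guide, a ratio of 1.07. The median peak held 76.3 and 69.2 normalized reads, and the 5th and 95th percentiles of the mean over both groups were 20.4 and 605.

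A peak was called when the authors' adjusted p was under 0.05, with no fold minimum. Differences are the log2 mean with the Malat1 guide minus the log2 mean with the luciferase guide. For gene lists and annotation classes, each p-value was turned into a two-sided normal score carrying the sign of the authors' fold, and the scores of a list's peaks were compared with those of all other peaks by limma's cameraPR with a preset correlation of 0.01 (limma 3.58.1, R 4.3.3). The p-values were adjusted by Benjamini-Hochberg over the 16 lists and, separately, over the classes. The test is competitive: a list with a small positive median can score below the other peaks. The 16 lists were written before the data were examined and held 413 genes, with Rela on 2 of them. They covered chemokines, cytokines and growth factors of inflammation, the NF-kB pathway, the interferon response, the AP-1 family, epithelial genes, mesenchymal and EMT genes, lung lineage genes, gut and liver lineage genes, matrix and matrix remodelling, Malat1 neighbours, splicing and paraspeckle proteins, cell cycle genes, housekeeping genes, leukocyte markers, and endothelial and fibroblast markers.

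Unless marked otherwise, the peaks named below were chosen by a rule written before the data were examined. It takes every Malat1 peak, the 10 genes per direction with the smallest p among called peaks (1 peak per gene, without predicted gene models), up to 3 genes per list with the smallest p, and Ccl2. The rule also asked that both libraries of a group lie on the same side of the other group, which was not checked because the per-library columns were left out. Gene assignments are the authors' and mostly name a neighbouring gene, often far from the peak, and an exon or intron class can refer to a transcript outside the RefSeq bounds of the assigned gene. Of 18766 gene identifiers, 18754 were found in a RefSeq gene table of the same assembly.

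The alternatives were a stricter adjusted p of 0.01, a minimum 2-fold change by the authors' fold, a minimum mean of 10 normalized reads, peaks within 3 kb or 50 kb of the start site, and centring of the differences along abundance in 50 bins. Further alternatives were added after the data had been seen: centring on the median of all peaks, on each chromosome's median and on the median of 10 Mb windows, a preset correlation of 0.05, ranks in place of scores, and the mean score of each gene's peaks. Centring moved each score by the shift over an error approximated from the difference and its score, or from the abundance bin where the score was under 1 in size, so these adjusted p are approximate. Of the centrings, only that on the median of all peaks was tested, on simulated data drawn from these approximate errors for the 80881 peaks. In each simulation 200 peaks were changed and a single shift of 0.2 on the log2 scale was added to all. The median difference in the data was 0.09. A shift equal for all peaks is removed by its median by construction, and centring along abundance, by chromosome or by window was not simulated. After centring on the median, 1.0% of the peaks changed by 0.5, 24.5% of those changed by 1 and 72.5% of those changed by 2 on the log2 scale were recovered. False calls numbered 1, 4 and 8 after centring and 77, 97 and 159 without it. In 100 simulated draws of unchanged scores over the same peaks, 0.375% of list p-values fell under 0.05. The scores were drawn independently while the test assumed a correlation of 0.01, so a low rate followed from the setting. It does not give the error rate for neighbouring peaks that move together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Motif and GC content checks were not run because they need a genome sequence, which was not used here.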

Results

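The series asks whether raising Malat1, a long noncoding RNA of the nucleus, changes which parts of the chromatin are open in KPC cells, a lung adenocarcinoma line from a KP mouse tumour. Cells with a Malat1-targeting guide (mA2 dRNA) were compared with cells carrying a luciferase-targeting guide (Con dRNA), with 2 libraries in each group. All read values are the authors' mean normalized reads per peak and group from the authors' deposited table, in mm10 coordinates. No spread between libraries or depth of a library was computed, since the per-library columns carry no sample name and were not used, so no error is printed beside these means, and whether a difference exceeded the replicate error rests on the authors' adjusted p alone. A peak is described as called, risen or fallen where the adjusted p in the authors' deposited table was under 0.05, by a test that is not given in the sources used here.

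Of the peaks around Malat1 itself, a single peak upstream of the gene rose. Malat1 (gene ID 72289) lies on the minus strand of chromosome 19 from 5795690 to 5802672, and 13 peaks were assigned to it. In 12 of the 13 peaks the mean was higher with the Malat1 guide, with a median difference of 0.23 on the log2 scale and a range from -0.06 to 0.54. The peak over the start site, from 5802401 to 5802801, held 322 normalized reads with the Malat1 guide and 290 with the luciferase guide, with an adjusted p of 0.978 in the authors' deposited table. The second promoter peak, 0.812 kb upstream, held 758 and 789 reads with an adjusted p of 0.983 in the authors' deposited table.

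The called Malat1 peak lies 9.41 kb upstream of the start site in intergenic sequence, from 5812077 to 5812477, and held 991 against 684 normalized reads, a 1.45-fold rise with an adjusted p of 0.0279 in the authors' deposited table. The count was also 1 when p was adjusted over the list alone. Peaks of chromosome 19 had a median difference of 0.20, and each of 4 ways of centring the differences ended the call, with an adjusted p between 0.0954 and 0.372. Malat1 RNA was not measured by this assay, so these values do not check the labels.

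**Figure D1:**
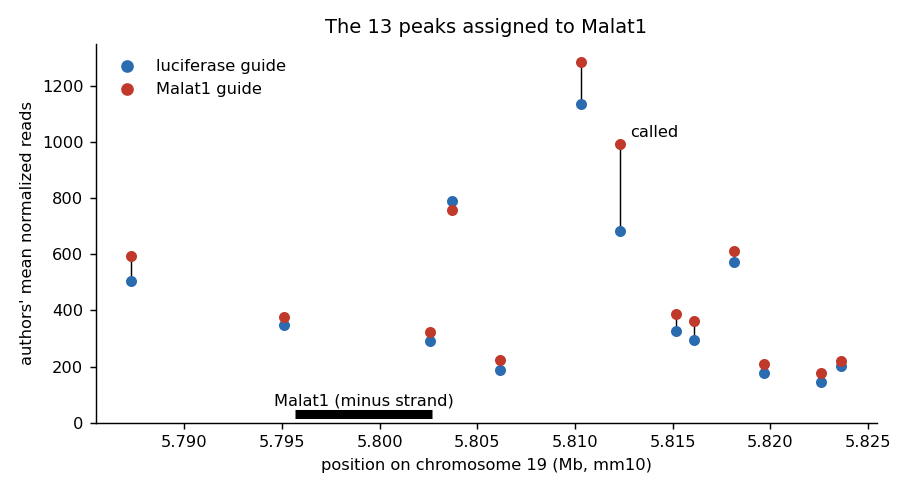
Authors' mean normalized reads (vertical axis) of the 13 peaks assigned to Malat1 by position on chromosome 19 (horizontal axis, Mb), with blue points for the luciferase guide, red points for the Malat1 guide and a black bar for the gene. The called peak rose from 684 to 991 reads, while the promoter peaks at 5.80 Mb stayed close together.

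Across the genome far more regions opened than closed with the Malat1 guide. Of 80881 peaks, 1801 were called higher and 410 lower by the adjusted p in the authors' deposited table, together 2.73% of the peaks and 1609 genes, of which 13 had calls in both directions. The median called rise was 2.88-fold and the median called fall 2.45-fold. The largest evidence for a rise came from a peak near Cdh5, the adhesion molecule VE-cadherin of endothelial junctions. It lies 78.2 kb upstream of the gene on chromosome 8, from 104023066 to 104023466, and held 636 reads with the Malat1 guide and 105 with the luciferase guide, a 6.05-fold rise with an adjusted p of 2.58e-19 in the authors' deposited table.

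Other peaks with strong rises lay near genes of several kinds. An intergenic peak 31.9 kb upstream of Grhl2, a transcription factor of epithelia, rose 9.97-fold from 19.1 to 191 reads, and a peak 7.30 kb from Foxs1, a forkhead factor, rose 2.97-fold to 795 reads. A peak 93.7 kb upstream of S1pr3, a sphingosine-1-phosphate receptor, rose 4.48-fold, and an intronic peak of Igfbp7, a secreted IGF-binding protein, rose 4.25-fold. Il34, a ligand of the CSF1 receptor, had a peak 2.72 kb upstream that rose 3.75-fold from 136 to 512 reads, with an adjusted p of 6.72e-10 in the authors' deposited table. The remaining genes named by the rule were Hao1 at 4.72-fold, Cplx2 at 4.44-fold, Irx1 at 4.89-fold and Insc at 7.02-fold. The Hao1 and Irx1 peaks lay 211 kb and 114 kb from the start site. The adjusted p of all 10 lay at or below 8.33e-10 in the authors' deposited table.

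Among regions that closed, an intronic peak of Tap2, which carries peptides to MHC class I, fell 2.97-fold from 397 to 134 reads, with an adjusted p of 1.31e-07 in the authors' deposited table. A peak near Galntl5 fell 4.37-fold and a peak near Slc39a10, a zinc transporter, 2.93-fold. An intronic peak 117 kb from the start site of Sema3d, a secreted semaphorin, fell 5.25-fold. A peak 421 kb from Esr1, the oestrogen receptor, fell 1.87-fold from 755 to 403 reads. An exonic peak of Lgr6, an R-spondin receptor, fell 3.15-fold. Trappc6b at 1.67-fold, Bnip1 at 3.92-fold, Pxylp1 at 3.10-fold and Zbbx at 6.65-fold lower completed the rule, with adjusted p up to 4.72e-06 in the authors' deposited table. The Zbbx peak lay 551 kb from the start site. None of these 10 rises and 10 falls lost its call under the centring alternatives.

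Higher peaks made up 81.5% of the calls, with a 95% Wilson interval of 79.8% to 83.0% that covers counting error only and treats peaks as independent. The median difference over all peaks was 0.09 on the log2 scale, and 60.8% of peaks had the higher mean with the Malat1 guide. With the differences centred on that median, 1307 peaks were called higher and 590 lower, a share of 68.9%.

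**Figure D2:**
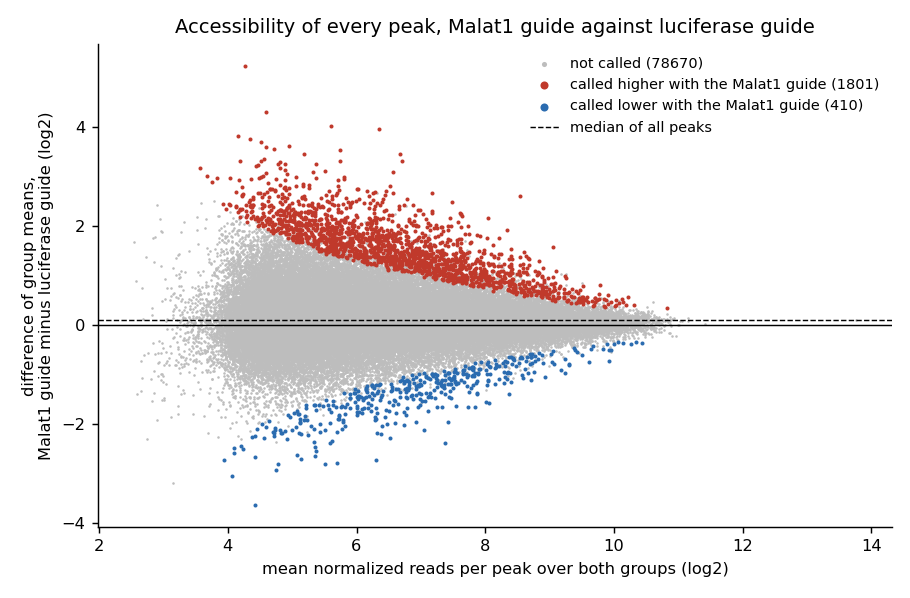
Difference of the authors' group means, Malat1 guide minus luciferase guide (vertical axis, log2), against the mean normalized reads over both groups (horizontal axis, log2), 1 point per peak. Red points are the 1801 peaks called higher and blue points the 410 called lower by the authors' adjusted p, and the dashed line marks the median of all peaks at 0.09.

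Peaks of extracellular matrix genes had higher scores, as a list, than the other peaks, a result that did not hold under every alternative. Of 293 peaks at 31 genes of matrix and matrix remodelling, 13 peaks of 6 genes were called higher and 0 lower, 17 higher and 0 lower when adjusted over the list alone, with a median difference of 0.28 (limma cameraPR adjusted p = 9.77e-04). An intergenic peak 24.0 kb upstream of Col5a1, a fibrillar collagen chain, rose 4.27-fold from 21.6 to 92.0 reads, and a peak near Col6a1, a collagen VI chain, rose 6.54-fold to 124 reads. Col6a2 had 2 called peaks, the better of which rose 1.94-fold to 703 reads. Named outside the rule, after their values were seen, Cd44, a hyaluronan receptor, had 4 higher calls among 28 peaks, and Lama5, a laminin chain, had 3 among 13. The adjusted p of this list ran from 1.45e-05 to 0.556 over the alternatives: it was 0.0636 with a mean score per gene, 0.0776 with that mean centred by 10 Mb window, and 0.556 with a preset correlation of 0.05, and no correlation was estimated because the per-library columns were not used.

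Peaks of mesenchymal and EMT genes also had higher scores, as a list, than the other peaks, with most of the calls at Ncam1 and Itgb3, and this too did not hold under every alternative. Over 224 peaks at 25 genes, 17 peaks of 5 genes were called higher and 1 peak of 1 gene lower, 28 higher and 4 lower when adjusted over the list alone, with a median difference of 0.25 (limma cameraPR adjusted p = 0.00345). Ncam1, a neural adhesion molecule, had 7 higher calls among 13 peaks, led by a peak 125 kb upstream that rose 3.06-fold from 92.8 to 284 reads. Itgb3, an integrin subunit, had 6 among 14, led by an exonic peak that rose 6.07-fold, with 2 of its peaks called after centring by 10 Mb window. The intronic Cdh11 peak, at a mesenchymal cadherin, rose 9.54-fold from 5.21 to 49.7 reads. Thy1 held the lower call. Vim, Zeb1, Snai1 and Twist1, which drive or mark the mesenchymal state and are named here after their values were seen, had no called peak. The adjusted p of this list ran from 3.38e-05 to 0.556 over the alternatives, with 0.0636 for a mean score per gene and 0.556 with a preset correlation of 0.05.

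Markers of endothelium and fibroblasts had 11 higher and 0 lower calls among 131 peaks, beside the matrix and mesenchymal calls, and 12 higher and 1 lower when adjusted over the list alone. The list itself did not pass the test (limma cameraPR adjusted p = 0.0695, with 0.0217 to 0.676 over the alternatives), and passed it when differences were centred along abundance, by chromosome or by 10 Mb window. Cdh5 had 5 higher calls among 6 peaks. Postn, a matrix protein of fibroblasts, had 3 among 4, led by an intergenic peak 119 kb from the start site that rose 5.28-fold to 132 reads. An intronic Cspg4 peak rose from 242 to 435 reads. Leukocyte markers had 0 higher calls and 1 lower call among 40 peaks, the same counts when adjusted over the list alone, at Laptm5, where a peak fell 2.51-fold from 251 reads (limma cameraPR adjusted p = 0.0719 for the list). The most significant peaks of S100a9 and Ly6g were not called.

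None of the lists of inflammation genes, which the series title points to, passed the main test, over all assigned peaks and without centring. Cytokines and growth factors had 8 higher and 0 lower calls among 201 peaks (3.98%, against 2.73% of all peaks called in either direction), 9 and 0 when adjusted over the list alone, and the list did not pass the test (limma cameraPR adjusted p = 0.193, with 8.27e-04 to 0.715 over the alternatives). It passed with peaks within 3 kb (8.27e-04) or 50 kb (0.0140) of the start site, with centring by 10 Mb window (0.0106) and with a mean score per gene centred that way (0.00567). Il34 held 4 of the 8 calls. A promoter peak of Tnfsf15, a TNF family ligand, rose 4.75-fold from 10.2 to 48.4 reads, and an intronic peak of Tgfb2, a TGF-beta ligand, rose 3.50-fold, though centring by window ended the first call (0.0847) and centring along abundance the second (0.0524).

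Chemokine peaks did not pass the test as a group (limma cameraPR adjusted p = 0.692 over 137 peaks), and 1 was called, over all peaks and when adjusted over the list alone. It lies 62.9 kb upstream of Cxcl12, the ligand of Cxcr4, and rose 6.69-fold from 6.57 to 43.9 reads. The leading Cxcl16 and Ccl9 peaks, both at promoters, held 120 against 55.7 and 515 against 343 reads, with adjusted p of 0.0578 and 0.128 in the authors' deposited table. Ccl2, a monocyte chemoattractant on chromosome 11 from 82035577 to 82037452, had 6 peaks, 5 of them with the higher mean under the Malat1 guide, and 0 called. Its leading peak, from 82038541 to 82038941, lies past the end of the RefSeq gene in sequence the authors annotated as an exon, and held 250 against 142 reads with an adjusted p of 0.239 in the authors' deposited table, and its promoter peak held 632 against 509. Adjusted over the list alone, 0 of the 6 Ccl2 peaks were called and the smallest p was 0.0582, while 2 had an unadjusted p under 0.05 in the authors' deposited table.

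The NF-kB pathway had 1 higher and 2 lower calls among 185 peaks, both over all peaks and adjusted over the list alone (limma cameraPR adjusted p = 0.240, with 0.00920 to 0.715 over the alternatives). The lower ones were a peak near Traf1, which fell 3.88-fold from 193 to 49.8 reads, and a peak 61.2 kb upstream of Traf3, which fell 2.73-fold. The higher one was an exonic Ikbkb peak, 1.92-fold, whose call ended with centring by chromosome (0.0578) or by window (0.129). The list passed the test with peaks within 3 kb of the start site (0.00920). The interferon response had 2 higher calls, at Socs1 and Irf1, and 1 lower, at Tap2, among 108 peaks, both over all peaks and adjusted over the list alone (limma cameraPR adjusted p = 0.757). Its median difference was 0.05, yet its scores lay below those of other peaks. Centring by chromosome or window ended the 1.56-fold Socs1 call (0.277 and 0.174), and all 4 centrings ended the 1.60-fold Irf1 call (0.106 to 0.145). In the AP-1 family, Fosl2 had 2 higher calls, led by a 2.79-fold rise, and Fosb 1, a 1.48-fold rise that no centring kept (0.0598 to 0.178), with 3 calls also when adjusted over the list alone, while the list did not pass (limma cameraPR adjusted p = 0.818 over 98 peaks). A Mafk peak, 1.30-fold lower and not called, was called after centring on the median (0.0155) or along abundance (0.0226).

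Epithelial and lineage lists did not pass the test, though some of their genes rose or fell. Among 113 epithelial peaks 3 were called higher and 0 lower, the same when adjusted over the list alone, with the Grhl2 peak above and a 2.49-fold rise 6.27 kb upstream of Krt8, a keratin of simple epithelia (limma cameraPR adjusted p = 0.240). The leading Krt18 peak was 1.94-fold higher and not called. Lung lineage genes had 5 higher and 2 lower calls among 120 peaks, 6 and 2 when adjusted over the list alone (limma cameraPR adjusted p = 0.636, with 0.0218 to 0.965 over the alternatives). An intronic Pdpn peak rose 2.31-fold, and 1 of 31 Foxa2 peaks, 44.7 kb upstream, rose 2.20-fold. A promoter peak of Sox2, a factor of airway progenitors, fell 3.04-fold from 151 to 49.8 reads. The median difference of the lung lineage list was 0.03 while its scores lay below those of other peaks, and the list passed downward with peaks within 3 kb of the start site (0.0218). Gut and liver lineage genes had 3 higher and 2 lower calls among 61 peaks, 3 and 3 when adjusted over the list alone. The promoter peaks of Pdx1 and Cdx2, homeobox factors of pancreas and intestine, rose 3.17-fold and 2.28-fold. Both lie in the same 1 Mb window of chromosome 5, from 147 Mb, which held 6 higher calls, so they may not be separate changes. An intronic Gata4 peak fell 4.71-fold from 35.2 to 7.47 reads. The gut and liver list did not pass (limma cameraPR adjusted p = 0.240, with 0.00696 to 0.965 over the alternatives). Its direction turned upward near start sites (0.00696 within 3 kb), over only 11 peaks. The Cdx2 call ended with centring on the median (0.0504) or along abundance (0.0525).

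Lists of general cell functions had no called peaks. Splicing and paraspeckle proteins, cell cycle genes and housekeeping genes had 0 calls among 88, 107 and 109 peaks by the authors' adjusted p, also 0 when adjusted over the list alone, with limma cameraPR adjusted p of 0.349, 0.861 and 0.753. Their median differences were 0.02, 0.07 and 0.03, below the 0.09 of all peaks, and their scores lay below those of other peaks. At an unadjusted p under 0.05 in the authors' deposited table they had 2, 6 and 7 peaks. Of all peaks 2.73% were called, so few calls could fall in lists of this size. Within 3 kb of a start site lay 32, 42 and 29 of their peaks, and promoter peaks had 1.20% higher calls and a median difference of 0.07. Whether the counts of 0 fall below what peak number and class give was not tested. The lowest p in these lists belonged to a Tra2a peak, 3.37-fold lower, a Ccnd1 peak, 3.78-fold higher, and a Ywhaz peak, 3.26-fold higher, none of them called. Malat1 neighbours had 0 calls among 64 peaks, 0 when adjusted over the list alone and 8 at an unadjusted p under 0.05 in the authors' deposited table, with a median difference of 0.16 (limma cameraPR adjusted p = 0.193, with 0.00696 to 0.878 over the alternatives). They passed upward with peaks within 3 kb of the start site (0.00696), and their direction against other peaks turned downward once differences were centred by chromosome (0.236) or by window (0.543). Peaks near Tm7sf2, Pcnx3 and Rnaseh2c were the leading ones and were not called.

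**Figure D3:**
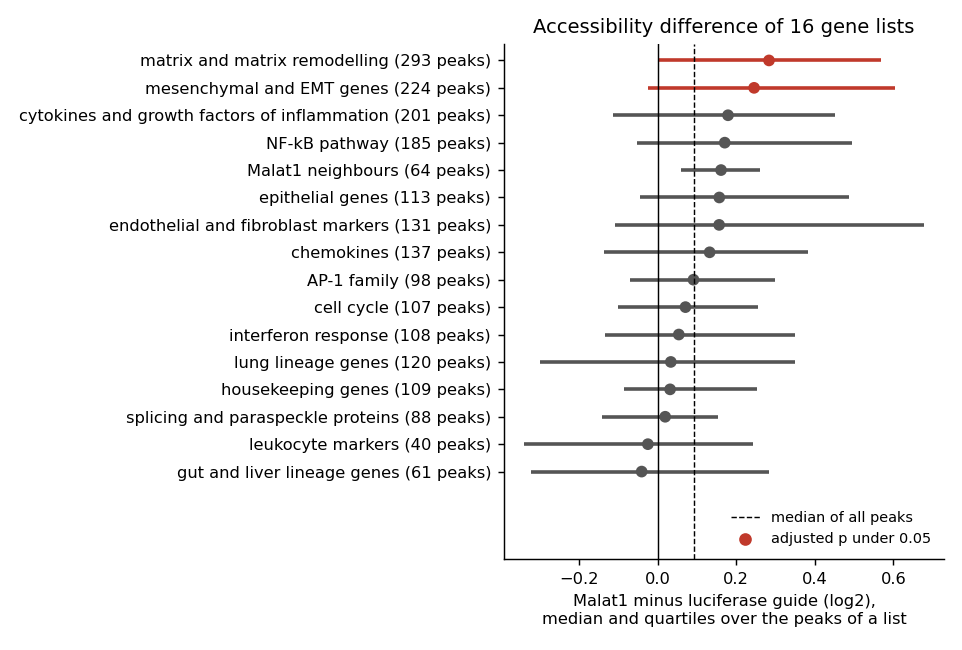
Difference of the authors' group means, Malat1 guide minus luciferase guide (horizontal axis, log2), for the 16 gene lists (vertical axis), with points at the median and bars from the first to the third quartile over a list's peaks. Matrix genes at 0.28 and mesenchymal genes at 0.25, in red, had a cameraPR adjusted p under 0.05, and the dashed line marks the median of all peaks at 0.09.

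Most calls lay away from promoters. Of 13620 promoter peaks, all within 1000 bp of a start site, 164 (1.20%) were called higher and 30 (0.22%) lower, against 694 (2.58%) and 165 (0.61%) of 26943 distal intergenic peaks and 765 (2.47%) and 174 (0.56%) of 31030 intron peaks. Promoter peaks held more reads, with a median of 272 against 59.5 for intron peaks. No class passed limma cameraPR, with adjusted p from 0.798 to 0.923. That test compares mean signed scores and not the share of peaks called. Its preset correlation also keeps the error of a mean from shrinking with many peaks, so a small shift of a large class could not pass. It therefore does not decide whether the classes differ, and the shares called were not tested. The promoter peaks with the smallest p, chosen after the values were seen, were those of Dpysl3, a cytoskeletal protein of neurons, which rose 3.93-fold, Gprin3 (3.93-fold), Ppara, a lipid-sensing nuclear receptor (3.34-fold), and Plcl1 (4.16-fold). Chosen in the same way, Jup, the junction protein plakoglobin, had a promoter peak that rose 1.72-fold from 542 to 934 reads, and the Elfn1 promoter fell 3.17-fold from 232 to 73.3 reads.

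The ratio of the groups differed between chromosomes and also within them. The median difference was 0.26 on chromosome 16, 0.23 on chromosome 13, 0.21 on chromosome 15 and 0.20 on chromosome 19, against -0.02 on chromosome 3 and -0.12 on chromosome X. The medians of promoter and distal peaks were 0.20 and 0.29 on chromosome 16 and -0.17 and -0.10 on chromosome X, while they differed in sign on chromosomes 1 (-0.04 and 0.02), 5 (-0.04 and 0.02) and 6 (-0.01 and 0.03). Windows of 10 Mb on chromosome 1 ran from -0.27 at 180 to 190 Mb to 0.28 at 40 to 50 Mb. Chromosome 15 had 186 higher and 16 lower calls among 3984 peaks, and chromosome X 9 of each among 1854. Chromosome Y, with 12 peaks and 0 calls, is left out here.

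**Figure D4:**
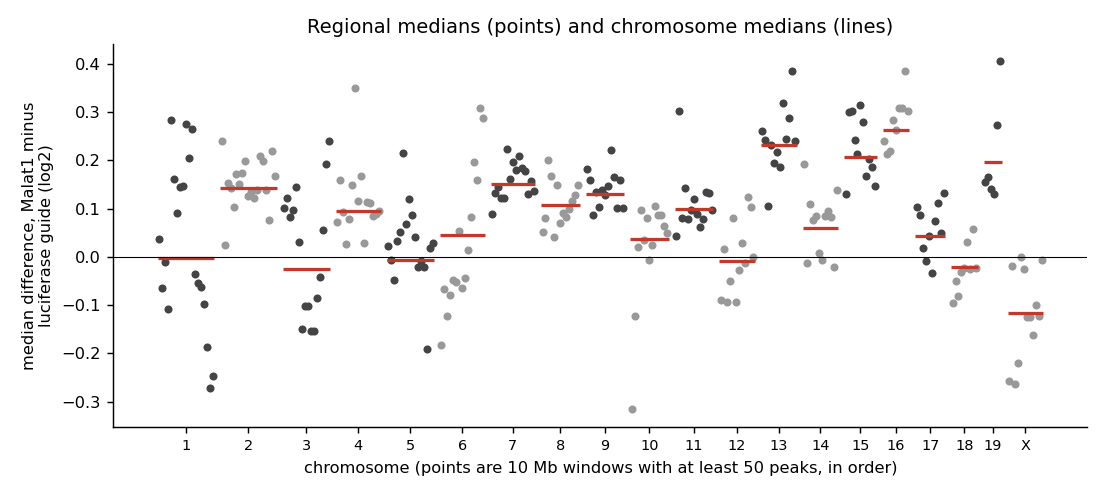
Median difference of the authors' group means, Malat1 guide minus luciferase guide (vertical axis, log2), for windows of 10 Mb with at least 50 peaks in order along each chromosome (points) and for whole chromosomes (red lines). Chromosome 16 lies highest at 0.26 and chromosome X lowest at -0.12 among the chromosomes drawn.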

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

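Centring on the median of all peaks, by chromosome and by 10 Mb window, and the correlation, rank and per-gene alternatives were chosen after the data had been seen, and the others before. No paired analysis was possible because the columns used are group means and the per-library columns, left out by choice, carry no replicate numbers. Leaving out libraries, further library scalings, other tests of library counts, pseudocounts, fry and estimated correlations were not run because those columns were left out, and a promoter limit of 1 kb is not an alternative since the promoter class already ends there. A minimum mean of 10 reads left out 137 peaks and changed no call. An adjusted p of 0.01 left 1036 calls, 867 higher and 169 lower (83.7% higher), and a minimum 2-fold change by the authors' fold left 1248, 1063 higher and 185 lower (85.2% higher), fewer by construction. The share of higher calls was 68.9% when centred on the median of all peaks, 69.7% along abundance, 71.2% by chromosome, with 1179 higher calls, and 70.7% by 10 Mb window, with 1068 higher calls. Malat1 had 0 called peaks under each of these 4 centrings, which lower its difference by the shift they remove. Of 56 named called peaks, 50 to 52 were still called under centring.

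Called lists numbered 2, against 4 with centring by 10 Mb window, 7 with peaks within 3 kb, 0 with a preset correlation of 0.05 0 with a mean score per gene and 2 with that mean centred by 10 Mb window (cytokines 0.00567, mesenchymal genes 0.00739). Malat1 neighbours reversed when centred by chromosome (adjusted p 0.236) or by window (0.543). Gut and liver genes reversed within 3 kb (0.00696), within 50 kb (0.965), per gene (0.873) and per gene with window centring (0.344). AP-1 within 3 kb (0.997), cell cycle within 3 kb (0.997) and per gene (0.962), and leukocyte markers per gene with window centring (0.579) also turned, without a call. Distal intergenic peaks turned along abundance (0.905), by chromosome (0.775) and by window (0.727), and promoters with ranks (0.917). Apart from what the centring itself removes, the cause was not tested. Over all lists and alternatives, 135 results stayed on the same side, 10 became called, 5 lost the call and 10 reversed. In the simulation 24.5% of peaks changed by 1 on the log2 scale were recovered, and how far the reads per peak limit this was not tested.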

Other observations

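The genes, families and windows described here, the slope across chromosomes, the shuffled calls and the chromosome 19 test were chosen only after the data had been seen. Some genes had many higher calls among the peaks assigned to them, which can lie far from the gene. Rgs3, a regulator of G protein signalling, had 7 higher calls among 9 peaks, Igfbp7 and Foxl1, a forkhead factor, 7 of 9 each, and Flrt2, a membrane adhesion protein, 7 of 15. The called peak with the smallest p lay 145 kb from the start site for Rgs3, 20.5 kb for Igfbp7, 59.7 kb for Foxl1 and 1.75 kb for Flrt2. The Rgs3 count fell to 4 under each of the 4 centrings. Over 22 genes whose symbols open with Rgs, 13 of 79 peaks in 5 genes were called higher and 0 lower, with Rgs1, Rgs2 and Rgs13 called in the same 1 Mb window of chromosome 1 and a median difference of 0.35. Among 197 families of symbols scanned this way, Rgs was called upward (limma cameraPR adjusted p = 0.00421), also per gene (0.0359) and under all 4 centrings (3.82e-05 to 0.00198). Rgs3 held 7 of the 13 calls and the chromosome 1 window 5, so few loci carry this result, and the per-gene test counts neighbouring genes separately. A preset correlation of 0.05, under which no fixed list was called, was not run for the families. The integrin beta family Itgb was called upward (0.00602) but not per gene (0.932) nor when centred by chromosome (0.0630) or window (0.0924), and the vomeronasal receptors of the Vmn family downward (0.0251) but not per gene (0.916) nor under any of the 4 centrings (0.0545 to 0.247).

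Falling peaks were fewer and some lay close together. Windows of 1 Mb with 5 or more lower calls numbered 3, at chromosome 14 from 63 Mb with 7 lower calls at Blk, Fam167a and Gata4, chromosome 5 from 25 Mb with 5 at Galntl5 and Prkag2, and chromosome 6 from 31 Mb with 5 at Mir29a, Mir29b-1 and Podxl. Kit, a receptor tyrosine kinase, had 3 lower calls among its 4 peaks. The leading one, intergenic and 158 kb from the start site, was 6.96-fold lower, from 79.3 to 11.4 reads. Tlr2, a receptor for bacterial lipoproteins, had 3 lower calls among 11 peaks, of which 0 remained called after centring by 10 Mb window. The richest window for rises was chromosome 9 from 116 Mb, where 16 of 25 peaks were called higher. Most of these calls were assigned to a predicted gene, and fewer than 5 to Tgfbr2, a TGF-beta receptor.

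Chromosome medians ran from -0.12 on chromosome X to 0.26 on chromosome 16, leaving out chromosome Y with its 12 peaks. A different mix of peak classes and abundances is argued against, since removing the medians of class and abundance left the SD of the 20 chromosome medians at 0.0992 against 0.0986 before, a ratio of 1.01. Across chromosomes, promoter medians followed distal medians with a slope of 0.927 (95% bootstrap interval 0.850 to 0.982). The interval resampled peaks within each chromosome as if independent, so it leaves out variation between chromosomes and libraries. Within chromosomes the promoter and distal medians of 258 windows of 10 Mb, which are not independent replicates, correlated with r = 0.573. A difference in DNA copy number would give such a slope and correlation. A candidate explanation is therefore that the populations with the 2 guides differ in the dosage of whole chromosomes or large parts of them. A guide effect on whole chromosomes or large regions would give the same pattern and stays open, untested, because the series has 1 contrast. Whether both libraries of a group carry these shifts was not checked, since the per-library columns were left out, so a difference between single libraries also stays open.

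The excess of higher calls, 81.5%, is argued not to come from library scaling alone, since centring on the median of all peaks left 68.9%. Shifts over stretches of 10 Mb or more alone are argued against in the same way by the 70.7% that centring on 10 Mb windows left. Centring on windows of that size does not remove shifts over shorter stretches, so it decides nothing about those. Both corrections lowered the share, so part of the excess may come from scaling or another shift common to all peaks. Centring on windows also removes such a shift, and its 70.7% was not below the 68.9% of the median alone. These shares therefore give no sign of a further part from regional shifts. An effect of the Malat1 guide on accessibility stays open as a hypothesis, as does a difference in signal over background between libraries, for which no value per library was used.

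Higher calls gathered in 79 windows of 1 Mb with 5 or more of them, which held 524 calls (29.1%), against 37 at most in 1000 shuffles of the calls within abundance bins, so chance placement is argued against. A local DNA gain would raise promoters with distal peaks, and outside chromosome 19 from 46 to 58 Mb the median difference was 0.14 for promoter and 0.36 for distal peaks of these windows, a ratio of 0.396 (95% bootstrap interval 0.334 to 0.454). The windows were chosen by their calls, which fall on distal peaks more often (2.58% against 1.20% of promoter peaks), so this ratio decides nothing and a gain stays open there. In the chromosome 19 segment, 53 of 513 peaks were called higher and 2 lower, the median difference was 0.48 against 0.15 elsewhere on the chromosome, and promoters rose by 0.818 of the distal rise relative to the rest of the chromosome (0.581 to 1.10), but the segment was also picked for its calls, so a DNA gain there and a regional effect of the guide cannot be told apart. Other windows, among them chromosome 9 from 116 Mb and those of Flrt2 and Ncam1, may reflect regulatory domains that opened together, a hypothesis for which no test was run, or a difference between the cell populations.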
